A study of Mus musculus with 9 samples.

How the data were processed

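Reporter RNA from FAIRE-STARR-seq was measured in E14 mouse embryonic stem cells with LIF (3 samples) and without LIF after RA (3 samples), next to the plasmid input (1 sample). RARA ChIP-seq after RA had 1 sample and 1 input sample. Per the labels' protocols, the plasmid library was made from accessible DNA of RA-treated cells, each biological replicate combined 4 transfections, and cDNA carried a molecular identifier of 8 random nucleotides. Samples were grouped by their titles. Cells with LIF and with RA came from the same transfections, but the deposited lists hold no value per replicate.

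Per the submitters' processing notes, Bowtie2, UMI-tools, SAMtools, MACS2 and deepTools were used and the genome build was mm9; their order, settings and versions are not given in the sources used here. The peak lists have no header. Their peak names speak of merged replicates and of LIF against the plasmid input (mESC enhancers), LIF against RA (LIF-dependent) and RA against LIF (RA-induced), so the authors called peaks on pooled samples. In each deposited list the columns gave a score of 10 times the −log10 q cut to a whole number, the fold enrichment at the summit (a ratio), the −log10 p, the −log10 q and the summit position. Fold enrichment and −log10 values are the authors' own peak values and were used to describe, rank and filter peaks within a list. The deposited table of scored mESC enhancers gave a further score per enhancer. How it was made is not given in the sources used here; across enhancers, which are not independent replicates, it followed log2 of the fold over input (Pearson r 0.794, slope 0.773), and it was read as a value of unstated scale. The highest peak number in the names was 28102 for mESC, 29683 for LIF-dependent, 20845 for RA-induced and 397053 for input regions, above the number of peaks listed, so these lists hold part of the numbered peaks; the filter is not given in the sources used here. A filter tied to another list would set how the lists nest.

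Rows that shared a region and differed in summit were collapsed to the row of highest −log10 q. This left 4674 of 4787 rows for mESC enhancers, 601 of 616 for LIF-dependent, 382 of 386 for RA-induced, 186959 of 195417 for input regions and 9757 of 11366 for RARA peaks. Regions were counted as shared when they overlapped by at least 1 bp. Coordinates are mm9 and counted from 1. No read counts or depths were given, so the precision of single peak values is unknown. Shares carry 95% Wilson intervals, odds ratios are conditional maximum-likelihood estimates with 95% exact intervals, and differences of medians carry 95% bootstrap intervals from 2000 resamples.

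Shares were compared with two-sided Fisher's exact tests, and medians with two-sided permutation tests of 100000 resamples (10000 for alternatives and tests added later). P-values were adjusted by Benjamini-Hochberg over 9 tests of RARA share, 9 tests of medians, 3 tests of the strongest RARA peaks and 4 tests of the X chromosome. For RARA at mESC enhancers the unit was the input region: the RARA calls of the 186959 input regions, in genome order, were shifted by 1000 random steps that could cross chromosomes, and the share in input regions holding an mESC enhancer was recomputed. This differs from the planned share over enhancers, and RARA peaks outside input regions did not enter it. Clustering was the share of regions whose midpoint lay within 12.5 kb of another of the list, against 1000 draws of input regions matched per chromosome. Stratified odds ratios are Mantel-Haenszel estimates with permutation of group labels within strata. On simulated regions with a planted odds ratio of 1.95 for RA-induced enhancers, the median estimate over 200 simulations of 4634 regions was 1.96, and 5.0% of simulations with no difference were called. With a confounder and no group effect, the unstratified test called 64.0% and the stratified test 3.5%. RARA calls were drawn independently for each simulated region, so these rates do not cover dependence between neighbouring regions. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.

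The named regions followed a rule written before the data were examined: the 10 RA-induced regions with the strongest RARA peaks, the 10 mESC and the 10 LIF-dependent enhancers of highest score, and the 10 strongest RARA peaks; other named regions are marked in the text. Alternatives changed the overlap definition, the RARA threshold, the region set and width, the comparison group, the statistic and the distances. The reference table at hand was of assembly GRCm38, not mm9, and coordinates were not converted. Nearest genes, promoter share, gene lists and motifs, planned before the data were examined, were therefore not analysed here, and regions are given by position alone.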

Results

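Enhancer activity was measured in E14 mouse embryonic stem cells by FAIRE-STARR-seq, a reporter assay in which fragments of accessible chromatin are cloned downstream of a promoter so that an active fragment transcribes itself. The fragments came from cells treated with retinoic acid (RA), a ligand of the nuclear receptors RARA, RARB and RARG. The library was transfected in 3 biological replicates, each split into cells kept with leukemia inhibitory factor (LIF), the cytokine that holds these cells in the pluripotent state, and cells without LIF that received 1 µM RA for 4 h. Binding of RARA after RA was mapped by ChIP-seq in 1 library with 1 input library. The deposited files held 3 enhancer lists, the regions of the plasmid input and the RARA peaks, all in mm9 coordinates. The lists came from merged replicates, so no value per replicate and no read depth was given, and the tests below treat regions, not cultures, as units. They compare the deposited lists and say nothing about the spread between cultures. Intervals on shares are 95% Wilson intervals and cover counting error alone.

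In cells with LIF, 4674 regions were listed as enhancers (mESC enhancers). They had a median width of 313 bp and together covered 1554 kb. Their fold enrichment over the plasmid input, the authors' value, had a median of 8.62 and reached 62.7. The deposited activity score, whose scale is not stated, ran from 0.445 to 5.42 with a median of 2.51. The highest score, 5.42, belonged to a region on chromosome 18 from 7608809 to 7609353. It was in neither of the lists of changed enhancers and overlapped an RARA peak of 2.64-fold enrichment. The second highest, 4.85, lay on chromosome 13 from 23833872 to 23834243 and was also LIF-dependent, with 6.13-fold enrichment of LIF over RA. A region on chromosome 2 from 153171126 to 153171571 had a score of 4.70 and the highest fold over input, 62.7, and was RA-induced by 5.24-fold. Of the 10 regions of highest score, 3 were LIF-dependent, 1 was RA-induced and 3 overlapped an RARA peak. mESC enhancers lay near each other more often than input regions did. Of them 4.56% had another within 5 kb and 33.9% within 50 kb, against means of 2.90% and 27.0% in 1000 draws of input regions matched by chromosome. At the distance set for the main comparison, between these, the share was 11.6%, against a mean of 7.75% (permutation p = 0.0020, two-sided, the smallest these draws can give). At that distance, for LIF-dependent enhancers (1.33% against 0.968%, permutation p = 0.687) and RA-induced enhancers (1.57% against 0.667%, permutation p = 0.260) no difference was called. The draws were not matched on input fold enrichment, with which mESC enhancers became more frequent. Whether this accounts for their clustering was not tested.

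Nearly all enhancers lay in DNA that the plasmid library was called to hold. A plasmid input region was overlapped by 98.9% of mESC enhancers (98.5 to 99.2%), 96.7% of LIF-dependent enhancers (94.9 to 97.8%) and 98.4% of RA-induced enhancers (96.6 to 99.3%). mESC enhancers were most frequent in the best represented DNA. In the decile of the 186959 input regions with the highest fold enrichment, 15.7% held an mESC enhancer, against 0.257% in the lowest decile. They were called over the plasmid input, so this gradient does not separate activity from the ease of calling a peak.

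The LIF-dependent list, which compares cells with LIF against cells given RA, held 601 regions, and 600 of them overlapped an mESC enhancer. Their LIF over RA fold enrichment had a median of 5.25 (quartiles 3.81 and 7.42). The exception, on chromosome 12 from 5062285 to 5063025, is named here because it is the single one, and its fold was 4.34. The filter of the LIF-dependent list is not given, and one tied to the mESC list would by itself produce such an overlap. The 10 LIF-dependent regions of highest score included one on chromosome 19 from 53841929 to 53842130 with a score of 4.34 and a fold of 25.7, the highest of the list. Another, on chromosome 1 from 184574527 to 184574788, had a score of 4.70 and a fold of 12.53. mESC enhancers that were LIF-dependent had a median score of 2.61, against 2.496 in the other 4074. The difference was 0.113 (95% bootstrap interval 0.046 to 0.184; permutation p = 0.0019, two-sided, adjusted p = 0.0044 over 9 tests). In the top quartile by score 16.3% were LIF-dependent, against 11.7% of the rest (odds ratio 1.47, 95% interval 1.21 to 1.77, Fisher's exact p = 7.91e-05). The LIF signal enters both the score and the LIF over RA call, so a higher score can follow from the selection of the list alone. The withdrawal of LIF and the addition of RA were made together, so the list does not separate them.

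The RA-induced list, from the opposite comparison, held 382 regions with a median RA over LIF fold enrichment of 5.47 (quartiles 3.98 and 7.51). None overlapped a LIF-dependent region. An mESC enhancer was overlapped by 195 of them (51.0%, 46.0 to 56.0%), and the other 187 lay outside the mESC list. The median fold was 6.48 in those outside and 4.47 in those at an mESC enhancer, a difference that the split itself can make, since the LIF signal is the denominator of the fold. Those outside lay in less well represented DNA, with a median input fold of 8.33 against 15.0. Like the LIF-dependent list, the RA-induced list does not separate the withdrawal of LIF from the addition of RA. In cells with LIF, the mESC enhancers overlapped by an RA-induced region had a median score of 2.47. The 3879 mESC enhancers in neither changed list (unchanged mESC enhancers) had 2.497. The difference of -0.026 did not pass the test (95% bootstrap interval -0.13 to 0.088; permutation p = 0.633). Absence from the mESC list is absence of a call and does not measure a lack of activity.

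RARA peaks were more frequent at RA-induced enhancers than at LIF-dependent enhancers or at mESC enhancers that were not LIF-dependent. Of the RA-induced regions 30.9% overlapped an RARA peak (118 of 382; 26.5 to 35.7%). Among mESC enhancers that were not LIF-dependent the share was 18.7% (760 of 4074; 17.5 to 19.9%), giving an odds ratio of 1.95 (95% interval 1.53 to 2.47; two-sided Fisher's exact p = 5.65e-08, adjusted p = 1.02e-07 over 9 tests). These mESC enhancers include the 195 that RA-induced regions overlap; without them the odds ratio was 2.13 (Fisher's exact p = 8.82e-10), a comparison chosen after the data were seen. LIF-dependent enhancers had an RARA peak in 16.6% (100 of 601; 13.9 to 19.8%). That was not told apart from the same mESC enhancers (odds ratio 0.870, 95% interval 0.685 to 1.10; Fisher's exact p = 0.259, adjusted p = 0.333). The 2 directions of change differed from each other, with an odds ratio of 2.24 for RA-induced against LIF-dependent enhancers (95% interval 1.63 to 3.08; Fisher's exact p = 2.59e-07, adjusted p = 3.89e-07). Input regions with no enhancer of any list overlapped an RARA peak in 2.48% of cases (2.41 to 2.55%).

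**Figure D1:**
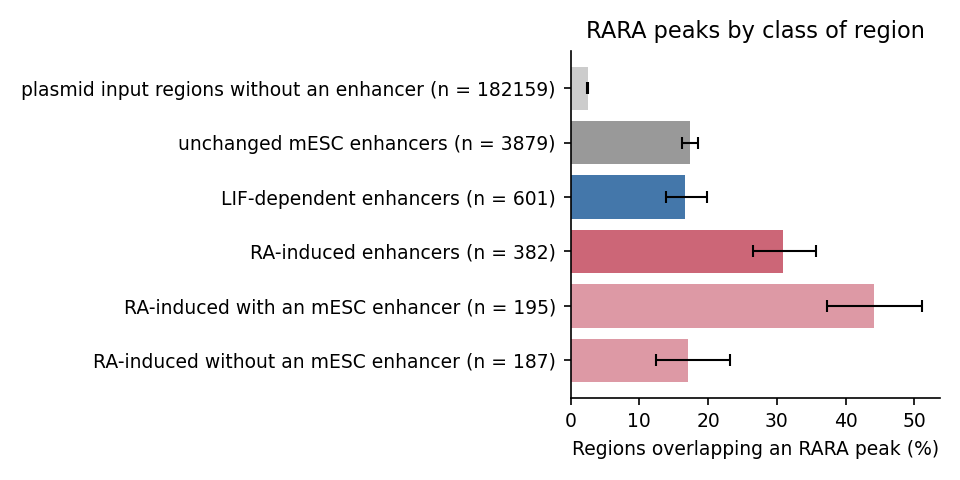
Share of regions overlapping an RARA peak by at least 1 bp, in percent, for 6 classes of region; bars are shares, lines are 95% Wilson intervals and n is the number of regions. RA-induced regions at an mESC enhancer stand at 44.1%, above the 17.1% of those outside one and the 17.3% of unchanged mESC enhancers.

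The excess lay in the RA-induced regions that overlapped an mESC enhancer. Of these 44.1% had an RARA peak (86 of 195; 37.3 to 51.1%), against 17.1% of those outside (32 of 187; 12.4 to 23.2%; odds ratio 3.81, 95% interval 2.32 to 6.35; Fisher's exact p = 1.12e-08, adjusted p = 2.51e-08). Unchanged mESC enhancers had 17.3% (16.2 to 18.6%), and the RA-induced regions outside the mESC list were not told apart from them (odds ratio 0.983, 95% interval 0.644 to 1.46; Fisher's exact p = 1.00). Their share was above that of input regions with no enhancer (odds ratio 8.12, 95% interval 5.36 to 12.0; Fisher's exact p = 1.20e-17). That comparison was not adjusted for input fold enrichment, whose medians were 8.33 and 5.36. The split by mESC enhancer was made after the values were seen. Within deciles of input fold enrichment the odds ratio against unchanged mESC enhancers was 3.95 for RA-induced regions at an mESC enhancer and 1.04 for those outside, again not called (permutation p = 0.918). Within quartiles of the RA over LIF −log10 q the odds ratio of regions at an mESC enhancer against those outside fell to 2.19, from 3.66 in the same regions (permutation p = 0.0045).

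The 10 RA-induced regions with the strongest RARA peaks had RARA fold enrichments from 17.7 to 32.0, and 9 of them overlapped an mESC enhancer. The first lay on chromosome 18 from 76331267 to 76331515, with an RARA fold of 32.0 and an RA over LIF fold of 5.11. The second, on chromosome 13 from 99881990 to 99882201, had an RARA fold of 31.3 and an RA over LIF fold of 6.30, and was the one outside the mESC list. On chromosome 2 from 20590028 to 20590300 the RARA fold was 28.0 and the RA over LIF fold 7.22. On chromosome 4 from 144624550 to 144624807 the RA over LIF fold was 12.6, the highest of the 10, with an RARA fold of 20.5 and a score in cells with LIF of 3.99. Chosen after the values were seen, the region of highest RA over LIF fold of the whole list, 20.3, lay on chromosome 19 from 37770294 to 37770533, outside the mESC list, with an RARA peak of 10.2-fold. Of the 10 regions of highest RA over LIF fold, 2 had an RARA peak.

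RARA peaks were also frequent at mESC enhancers as a whole, of which 18.5% overlapped one (866 of 4674; 17.4 to 19.7%). Of the 4618 input regions that held an mESC enhancer 20.3% overlapped an RARA peak. When the RARA calls were shifted along the input regions the mean was 2.94% and the highest of 1000 shifts 3.70% (ratio 6.91; permutation p = 0.0020, two-sided, the smallest these shifts can give). Within deciles of input fold enrichment this ratio fell to 2.81 (937 input regions with both, against 333 expected; permutation p = 1e-04, the smallest 10000 resamples can give), and the odds ratio from 9.94 to 4.25. This adjustment was chosen after the data were seen. The highest decile, where mESC enhancers were most frequent, is wide, with a median input fold of 13.5 and values up to 52.0. Differences of input fold within it stay unadjusted and may account for part of the remaining ratio. mESC enhancers with an RARA peak had a median score of 2.57, against 2.504 without, a difference of 0.063 that did not pass the test (95% bootstrap interval -0.015 to 0.128; permutation p = 0.0536, adjusted p = 0.0804). With log2 fold enrichment over input in place of the score the difference was 0.20 and passed (permutation p = 1e-04, the smallest 10000 resamples can give).

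The RARA list held 9757 peaks with a median fold enrichment of 3.06. Peaks at RA-induced enhancers were stronger, with a median of 5.13 against 3.32 at unchanged mESC enhancers (difference 1.81, 95% bootstrap interval 0.713 to 2.83; permutation p = 1e-05, two-sided, the smallest 100000 resamples can give; adjusted p = 9.00e-05). At LIF-dependent enhancers the median was 3.48, not told apart from unchanged ones (difference 0.161, 95% bootstrap interval -0.103 to 0.577; permutation p = 0.205). In the top decile of RARA peaks by fold 5.43% overlapped an RA-induced enhancer, against 0.740% of the rest (odds ratio 7.70, 95% interval 5.22 to 11.3; Fisher's exact p = 6.24e-23, adjusted p = 1.87e-22 over 3 tests). For LIF-dependent enhancers the shares were 1.64% and 0.957% (odds ratio 1.73, 95% interval 0.939 to 2.98; Fisher's exact p = 0.0623). Most RARA peaks were at no listed enhancer: 9.19% overlapped one of any list (8.64 to 9.78%), and 55.6% overlapped an input region (54.6 to 56.6%). The strongest peak, 98.7-fold, lay on chromosome 3 from 152395775 to 152397306, in an input region and outside every enhancer list. Of the 10 strongest, 7 overlapped an input region, 1 an mESC enhancer and 0 an RA-induced enhancer. The one at an mESC enhancer lay on chromosome 4 from 106051689 to 106052613 and had a fold of 50.4.

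**Figure D2:**
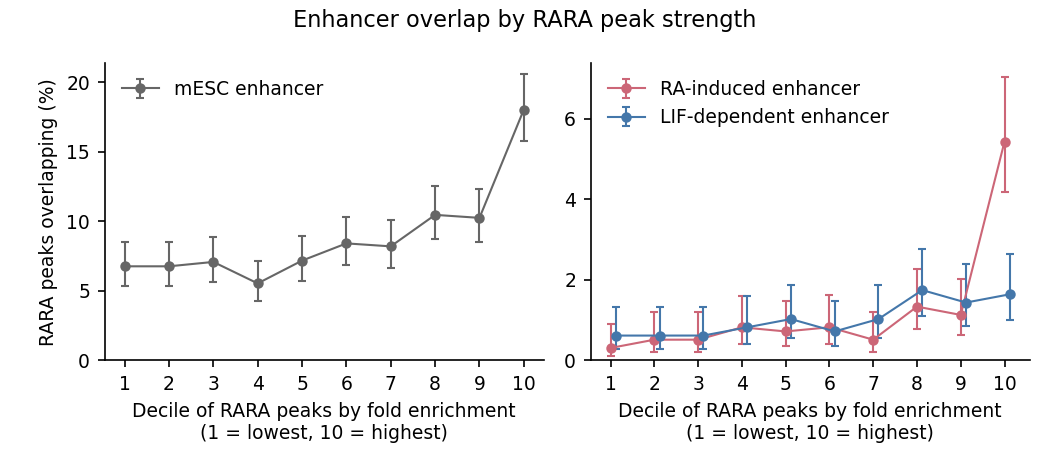
Share of RARA peaks overlapping an mESC enhancer (left) or an RA-induced or LIF-dependent enhancer (right), in percent, for deciles of the RARA peaks by fold enrichment; points are shares and lines 95% Wilson intervals. RA-induced overlap reaches 5.43% in the highest decile, where LIF-dependent overlap is 1.64%.

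Where an enhancer had an RARA peak, the RARA summit was nearer to the enhancer summit in RA-induced regions. The median distance was 36 bp in 118 RA-induced regions and 58 bp in 673 unchanged mESC enhancers (difference -22 bp, 95% bootstrap interval -31 to -7.0; permutation p = 0.0049, two-sided, adjusted p = 0.0087). In 100 LIF-dependent enhancers it was 50 bp (difference from unchanged -8 bp, permutation p = 0.321). RARA peaks at RA-induced regions were also stronger, and within quintiles of RARA fold enrichment the difference was -8.81 bp and no longer passed (permutation p = 0.207). The comparison was chosen after the data were seen. It sets unlike summits against each other: those of RA over LIF calls against those of LIF over plasmid input calls. RA-induced and LIF-dependent regions, both from calls between conditions, were not tested against each other for this distance.

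**Figure D3:**
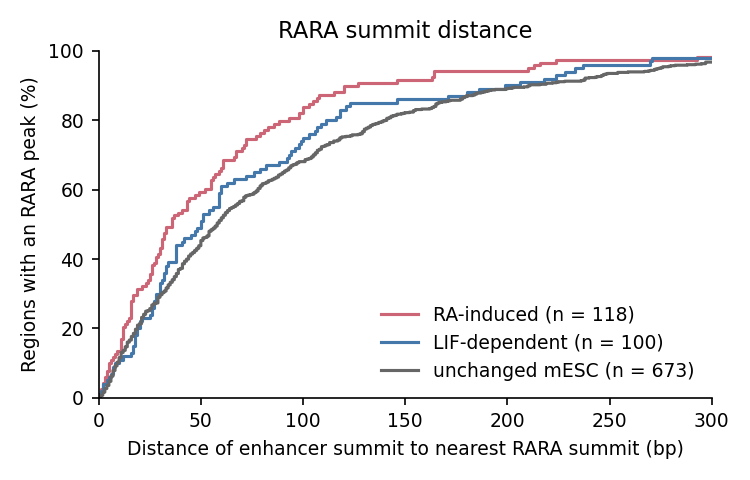
Cumulative share, in percent, of regions with an RARA peak by the distance in bp between the enhancer summit and the nearest RARA summit, for 3 classes of enhancer; n is the number of regions. Medians are 36 bp for RA-induced, 50 bp for LIF-dependent and 58 bp for unchanged mESC enhancers.

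Relative to the plasmid library, enhancers were more frequent on the X chromosome than on autosomes in all 3 lists. The X held 48.9 mESC enhancers per 1000 input regions, against 24.7 on autosomes (126 and 4548 enhancers; odds ratio 1.98, 95% interval 1.64 to 2.38; Fisher's exact p = 1.57e-11, adjusted p = 6.29e-11). For LIF-dependent enhancers the values were 6.21 and 3.17 (odds ratio 1.96, 95% interval 1.11 to 3.21; Fisher's exact p = 0.0129, adjusted p = 0.0131 over 4 tests). For RA-induced enhancers they were 6.99 and 1.97 (18 and 364 enhancers; odds ratio 3.54, 95% interval 2.07 to 5.68; Fisher's exact p = 9.01e-06, adjusted p = 1.80e-05). RARA peaks went the other way, with 40.4 per 1000 input regions on the X and 51.7 on autosomes (odds ratio 0.781, 95% interval 0.635 to 0.951, Fisher's exact p = 0.0131, adjusted p = 0.0131). The X value lay within the range of single autosomes, from 40.3 on chromosome 15 to 72.1 on chromosome 4. Since 44.4% of RARA peaks overlapped no input region, their number per input region is not a share of the library. The mESC excess was smaller in the strongest quintile of input regions, of which 11.6% on the X and 9.44% on autosomes held an mESC enhancer. Against input regions of the same fold enrichment, a comparison chosen after the data were seen, the ratio of X input regions holding an mESC enhancer to those expected was 1.27 (121 against 95.1; permutation p = 0.0045), down from 1.93 unmatched; matched in the same way, single autosomes ran from 0.863 to 1.21. For LIF-dependent enhancers it fell from 1.89 to 1.30 and was no longer called (15 against 11.5, permutation p = 0.377). Single autosomes ran from 0.648 to 1.35 for that list. For RA-induced enhancers it fell from 3.60 to 2.46 (18 against 7.32, permutation p = 7.00e-04), with single autosomes from 0.603 to 1.51. All these tests treat regions as independent.

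**Figure D4:**
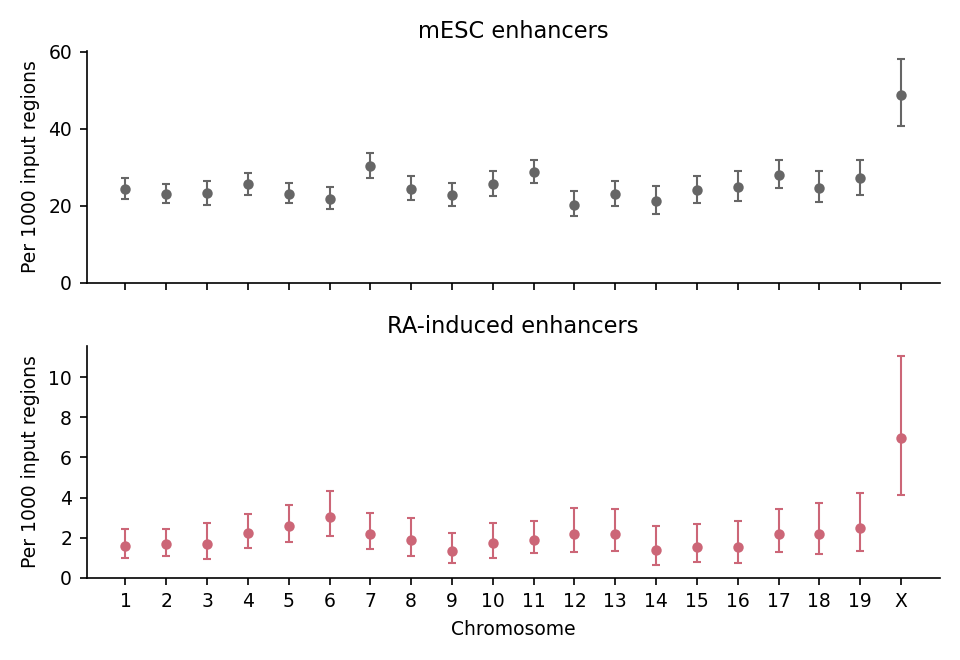
Number of mESC enhancers (top) and RA-induced enhancers (bottom) per 1000 plasmid input regions on each chromosome, with 95% exact Poisson intervals on the enhancer count. The X stands at 48.9 and 6.99, above every autosome in both panels.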

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

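The chromosomes left out in turn, the weighting by input fold enrichment and the split by mESC enhancer were chosen after the results were seen. The comparison with the stronger 50% of the RARA peaks was set before the data were seen, but what it should show for weak peaks was written after its result was seen.

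RA-induced and LIF-dependent enhancers differed in their share with an RARA peak, with an odds ratio of 2.24 in a test of the difference itself. The plasmid library came from RA-treated cells, so DNA bound by RARA may have been better represented. Within deciles of input fold enrichment the odds ratio against unchanged mESC enhancers was 2.26, which argues against input representation as the whole cause. Against mESC enhancers that were not LIF-dependent, leaving out each chromosome in turn gave at least 1.83, and the stronger 50% of the RARA peaks gave 2.33 in place of 1.95 with all peaks; against LIF-dependent enhancers the values were 2.13 and 2.58. The difference therefore did not rest on any single chromosome or need the weaker RARA peaks. Several chromosomes left out together were not tested. RARA peaks at RA-induced enhancers were stronger to begin with (median fold 5.13 against 3.32 at unchanged mESC enhancers). The rise with the stronger peaks follows in part from that, and it does not address strong unspecific peaks. Within deciles of input fold the odds ratio of RA-induced against LIF-dependent enhancers was 2.34. Activation by RA-bound receptor is a candidate explanation. The 2.34 is the flagged contrast itself, adjusted for input fold, so it cannot favour this explanation over others. From the lowest to the highest quartile of RA over LIF fold the RARA share was 22.9%, 37.9%, 37.5% and 25.3%, with no steady rise. Median input fold fell from 16.0 to 8.58 between these quartiles. Regions outside the mESC list had higher RA over LIF folds (median 6.48 against 4.47) and fewer RARA peaks. The shares were not adjusted for either, so they do not decide whether RARA overlap rises with the fold. RARA binding was not mapped in cells with LIF. As a hypothesis found on these lists receptor activation stays open to causes not tested. Among them are the withdrawal of LIF together with the addition of RA, the single ChIP library and the unstated filter of the lists.

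The share with an RARA peak was 44.1% in RA-induced regions at an mESC enhancer and 17.1% outside. Regions outside lay in weaker input regions, but within quartiles of input fold the odds ratio was 3.57. Their calls were also weaker, and within quartiles of the RA over LIF −log10 q it fell to 2.19, from 3.66 unstratified in the same regions, and still passed (permutation p = 0.0045), so call strength may account for part of the difference. No biological explanation was tested.

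Part of the RARA peaks and input regions lay in data that the comparisons of enhancer classes with each other do not use. Of the RARA peaks 118 were on the mitochondrial genome or on contigs without a position on a chromosome, where the input list held no region; they count in the shares of all RARA peaks. Of all RARA peaks 44.4% overlapped no input region. The input list held 11 regions on chromosome Y, with 0 enhancers.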

How the results depend on the processing

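The alternatives with a chromosome left out, weighted by or matched on input fold, restricted to a part of the RA-induced list, without RA-induced regions in the comparison, and with log2 fold for the score were chosen after the data were seen. RA-induced enhancers kept an odds ratio above 1.7 with a call in 15 of 16 alternatives; restricted to regions without an mESC enhancer it was 1.04 and not called, and that restriction itself shows where the excess lay. RA-induced against LIF-dependent enhancers stayed between 1.85 and 3.36, called in all 10. For LIF-dependent enhancers, not called in the main comparison, the direction turned to 1.07 with width-matched enhancers, still not called. Against input regions without an enhancer it turned to 7.85 and was called (Fisher's exact p = 3.30e-50). The median input fold of those regions was 5.36, against 12.3 in LIF-dependent enhancers. The score difference by RARA overlap, 0.063 and not called, was called in 6 of 10 alternatives: 0.087 with 50% of the region covered, 0.082 with the summit inside, 0.094 with the stronger RARA peaks, 0.070 in input regions, 0.066 on autosomes and 0.20 with log2 fold; with RARA peaks within 1 kb it was 0.014 (permutation p = 0.658); the cause was not tested. Input overlap moved to 98.0% (mESC) and 95.3% (RA-induced) at 50% cover, and to 91.4%, 82.9% (LIF-dependent) and 81.7% with the stronger input regions, which are fewer. RARA strength, the score of LIF-dependent enhancers, clustering and RARA at mESC enhancers kept direction and call in the alternatives run. For clustering these changed the distance alone. List sizes and the X excess per base pair (1.95, 1.92 and 3.48 for mESC, LIF-dependent and RA-induced) carried no test there. Against input regions of the same fold the X excess was 1.27, 1.30 and 2.46; the LIF-dependent one, 15 regions against 11.5, was no longer called (permutation p = 0.377). Not run for want of an mm9 annotation or genome: distance from TSS, promoter share, gene lists and motifs. Score per kb was not run, since the score did not grow with width (Spearman rho 0.053). No paired analysis was possible because the lists pool the replicates; leaving out a replicate was not possible either.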

Other observations

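The tests of X input strength, with that of single autosomes, and of the strongest input regions, of neighbouring LIF-dependent regions, of RARA summits within 10 kb and of summit distance were chosen after the results were seen; those within classes of width, RARA fold and input fold for the other patterns were written before their outcome.

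Among LIF-dependent enhancers the RARA share fell with the LIF over RA fold, from 20.5% and 24.3% in the lower quartiles to 12.8% and 8.67% in the upper ones. The stronger part had 10.7% and the weaker 22.4%, an odds ratio of 0.416 (Fisher's exact p = 1.18e-04, unadjusted), and 0.456 within quartiles of input fold. This split regroups the regions of the same quartiles, so it is not independent of the fall seen there. In RA-induced enhancers the shares were 22.9%, 37.9%, 37.5% and 25.3% from the lowest to the highest fold, with no single direction. These were not adjusted for input fold, whose median fell from 16.0 to 8.58. Across quartiles of score the RARA share of mESC enhancers was 17.4%, 17.9%, 17.6% and 21.2%.

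RARA peaks crowded in a few windows of 1 Mb. The densest, on chromosome 4 from 146000001 to 147000000, held 118, and the next, from 145000001 to 146000000, held 104, with 0 RA-induced enhancers in either. The one after these, on chromosome 13 from 66000001 to 67000000, held 94, with 4 RA-induced and 8 mESC enhancers on 53 input regions. In the 5 densest windows the RARA peaks per input region were at least 7.66 times the genome-wide ratio, which follows in part from picking windows by their RARA peaks. In order of density 21.2%, 23.1%, 23.4%, 17.6% and 65.3% of their RARA peaks overlapped an input region, against 55.6% of all RARA peaks. Their median RARA folds were 2.33, 2.35, 2.73, 3.04 and 5.12, against 3.08 on assembled chromosomes. The cause was not tested.

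mESC enhancers per input region were nearly doubled on the X, at 4.70% of input regions against 2.44% on autosomes. Against input regions of the same fold, 121 X regions with an enhancer stood against 95.1 expected, a ratio of 1.27 (permutation p = 0.0045). Single autosomes ran from 0.863 to 1.21 in the same comparison, and 5 of 19 passed the unadjusted permutation test, so input strength may account for much of the excess, and whether the rest goes beyond the spread between chromosomes cannot be told. E14 is a male line with a single X, which could leave weak X regions uncalled; in the strongest quintile of input regions the odds ratio was 1.26 (Fisher's exact p = 0.0465), below the 2.77 of the rest but not absent, so this cannot be told apart from other causes with these lists. No biological explanation was tested.

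The median distance between RARA and enhancer summits differed by -22 bp between RA-induced and unchanged enhancers, by -19.0 bp within quintiles of region width (permutation p = 0.0220) and by -8.81 bp within quintiles of RARA fold (permutation p = 0.207). A LIF-dependent region lay within 50 kb of 4.97% of RA-induced and 4.51% of unchanged enhancers, an odds ratio of 1.11 whose interval, 0.643 to 1.81, leaves a moderate excess open. RA-induced regions without an RARA peak had one within 10 kb in 18.6% of cases, against 18.2% of such unchanged enhancers (odds ratio 1.03, 95% interval 0.728 to 1.43).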
